A study of Mus musculus with 25 samples.

How the data were processed

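Liver RNA from 25 male C57BL/6J mice was profiled, 5 mice in each of 5 groups. C57BL/6J is the common inbred laboratory mouse strain. 1 group was kept on chow. The other groups received the HFCFr diet, which per the labels held 40% of its energy as fat, 2% cholesterol and 20% fructose, for 32 weeks. From week 20, per the labels' protocols, diet-fed mice received 1 of 4 treatments. Null mice received a control virus, AAV8-TBG-Null. GSK mice received the control virus and GSK2330672 in the diet at 8 mg/kg/day. FGF mice received AAV8-TBG-FGF15. Combination mice (GSK plus FGF) received AAV8-TBG-FGF15 and GSK2330672. GSK2330672 inhibits the ileal bile acid transporter, which takes bile acids back up from the gut. AAV8 is a viral vector that reaches the liver, and TBG is a promoter active in hepatocytes. FGF15 is the hormone by which the intestine signals to the liver to lower bile acid synthesis. The viral dose was 1e+11 genome copies by tail vein. The labels of the chow mice name no vector.

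Libraries were made with a QuantSeq 3' mRNA-Seq FWD kit, per the labels' protocols. Such a kit places 1 tag near the 3' end of each polyadenylated transcript. Reads were aligned with GSNAP to mm10 and handled with SAMtools and Cufflinks, per the submitters' processing notes. The sources used here do not state how multi-mapping reads, strand or low values were treated. The deposited table holds 43548 genes in 25 columns, 1 per library, without pooling. Its header gives no unit. The authors' values were read as FPKM (fragments per kilobase of transcript, scaled to the mapped total), from the values themselves and because Cufflinks was named, so this unit is inferred. FPKM divides by transcript length, which tags at the 3' end do not scale with. Levels of different genes are therefore not compared, and only the same gene is compared across libraries. All 37 genes with names starting in mt- were listed at 0 in every library, so no mitochondrial share could be had.

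Gene identifiers were looked up in GENCODE M21 (GRCm38, mm10), where 42470 of them (97.5%) were found. Symbols and coordinates come from that annotation. In the deposited name column, 27 names had been turned into dates and 165 were repeats, so genes were followed by identifier. The list members Tf, Hbb-b1 and Hbb-b2 matched no gene of the table. Genes of the Mup, Serpina1 and globin families have near-identical copies, and reads could be split between them, so the value of any single member is uncertain.

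FPKM totals were between 430775 and 553140 in 24 libraries. No read totals were used. Depth was estimated from the size of the smallest steps in genes with 1 annotated transcript. The estimates lay between 1950000 and 4900000 reads with a median of 2460000, and they are approximate. The number of genes above 0 was 13255 to 15973. FGF replicate 1 was almost empty. It held 169 genes above 0, with 99.6% of genes listed at 0 and albumin (Alb) listed at 0, and its estimate was 300 reads. It was left out on these technical grounds after the files were seen and before any test. The planned design had all 25 libraries in the fit, so the fit of 24 departs from it. Counts with all 25 are given beside the counts with 24.

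Genes with at least 1 FPKM in at least 5 libraries were kept (11226 genes). Values were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, using eBayes with a trend, 1 mean per group and 1 estimate of spread for all 24 libraries. Tests were two-sided with Benjamini-Hochberg adjustment over all tested genes at 0.05, without a fold minimum. Each adjusted p in the text is limma's unless another test is named. The comparisons were the diet (Null against Chow), each treatment against Null, the treated groups against each other, the combination against Chow, and the interaction. The interaction is the change from FGF to the combination minus the change from Null to GSK. Tables and plots were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.

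The comparisons, the 34 gene lists, the rule for named genes and most alternatives were chosen before the data were examined. The lists cover liver pathways and markers of cell types that liver RNA can hold. Lists with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. The neutrophil, T and NK cell, pancreas and adipose lists had too few members for this. For most lists the text gives how many members passed over all genes, and for some also how many when adjusted over the list alone. A list score is the mean of its members' log2(FPKM + 1) in a library minus the mean of the Chow libraries. Named genes were of 3 kinds. The first were the 7 largest rises and 7 largest falls among called genes whose groups did not overlap, whose higher group had a mean of at least 5 FPKM and whose symbol was not a clone name. The second were the 3 members with the smallest p in each list that passed camera. The third were 18 genes of bile acid, lipid and fibrosis biology fixed in advance. Comparisons between treated groups, the interaction and the combination against Chow used the 5 largest rises and falls. The text gives the members of this set that matter most, and any other gene is said to have been chosen after its values were seen.

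Because the Null libraries serve every treatment comparison, the share of diet-changed genes moved back was computed with the Null libraries divided between both sides of the comparison, over 20 divisions. For simulated unchanged groups a similar value was computed over 100 draws. Each draw used a single division and the genes called with all Null libraries, so it is not built exactly as the real median. Per-library slopes were compared with exact two-sided permutation tests. The fits were tested on simulated data with the real means and spreads, 50 genes being changed by each of 4 known amounts. All 4 amounts were present at once, changed genes were taken from those with higher Null levels, and noise was independent between genes. Recovery may therefore be lower where few genes change or where levels are low. For GSK against Null, 24% of 50 genes changed by 0.5 on the log2 scale were recovered, 66% of those changed by 1 and 96% of those changed by 2, among 11226 genes. For FGF against Null the shares were 16%, 62% and 88%, for the combination against Null 16%, 68% and 98%, and for Null against Chow 8%, 58% and 96%.

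Alternatives planned in advance were quantile normalisation, no filter, a pseudocount of 0.1, a fit of the compared groups alone, a replicate term and each library left out in turn. Median-ratio scaling was added after the data were seen. The fit of all 25 libraries was planned as the main fit and became an alternative once FGF replicate 1 was seen to be almost empty. Alternatives that need whole-number counts were not run, because the values are not counts.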

Results

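Gene expression was measured in the livers of 25 male mice, 5 in each of 5 groups. Chow mice ate a standard diet. Null, GSK, FGF and combination mice ate a diet rich in fat, cholesterol and fructose (HFCFr) for 32 weeks and were treated from week 20. Null mice carried an empty viral vector, GSK mice received an inhibitor of ileal bile acid uptake, FGF mice carried a vector for the bile acid hormone FGF15 in hepatocytes, and combination mice received both. The series asks whether bile acid treatments act on diet-induced fatty liver disease. The libraries used held an estimated 1950000 to 4900000 reads each. 24 libraries were compared, because FGF replicate 1 was almost empty (169 genes above 0), so the FGF group has 4 libraries and the others have 5. Libraries of the same group correlated with r between 0.914 and 0.961 across genes, over 46 pairs. The first principal component held 26.6% of the variance, with Chow libraries at -56.2 to -37.9, Null libraries at 26.3 to 37.4, GSK libraries at 18.1 to 27.4 and combination libraries at -27.3 to 4.9. The 4 FGF libraries lay far apart on it, at -18.9, -8.9, 18.9 and 21.6.

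The first comparison, Null against Chow, asks what the diet did to the liver. Null mice also carried the control vector while the labels of the chow mice name none, so diet and vector coincide here, and changes given as changes with the diet include any effect of the vector. Bile acid synthesis genes changed in both directions. Cyp7a1, the rate-limiting enzyme of the classical pathway, rose from 9.45 ± 5.91 to 51.5 ± 13.6 FPKM (SD, n = 5 each), a log2 change of 2.54 ± 0.48 (SE; limma adjusted p = 0.000298). Cyp8b1, which directs synthesis toward cholic acid, fell from 116 ± 15.7 to 48.2 ± 22.1 FPKM (log2 change -1.41, adjusted p = 0.000858). Cyp7b1, of the alternative pathway, fell from 287 ± 44.2 to 30.6 ± 6.99 FPKM (log2 change -3.20, adjusted p = 3.71e-07). In the bile acid synthesis list of 15 tested genes, 3 rose and 3 fell. Its mean change was -0.07 and its median 0.11, so they differ in sign, and its camera call (adjusted p = 0.0345) was lost with an estimated correlation (adjusted p = 0.149) and after quantile normalisation (adjusted p = 0.301). Slc10a1, which takes bile acids up from blood, had 126 ± 18.9 FPKM in Chow and 113 ± 25.4 in Null mice, without a call, and it passed the test with median-ratio scaling (log2 change -0.56). Abcb11, the bile salt export pump, had 32.3 and 26.8 FPKM (log2 change -0.27, adjusted p = 0.217), and it passed the test after quantile normalisation (log2 change -0.60) and with median-ratio scaling (-0.65).

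Genes of sterol and lipid handling changed with the diet. Cholesterol synthesis genes fell in 8 of 22 cases over all genes and in 9 when adjusted over the list alone, with a mean log2 change of -0.73 (adjusted p = 6.2e-13; adjusted p = 0.0831 with an estimated correlation). Cyp51, a demethylase of that pathway, fell from 50.3 ± 13.7 to 8.20 ± 2.09 FPKM. Targets of LXR, the receptor that senses sterols, rose in 9 of 10 cases (10 over the list alone; mean 1.47, adjusted p = 1.84e-06; adjusted p = 0.0544 with an estimated correlation). Among them, the sterol exporter gene Abcg5 rose from 8.89 to 41.1 FPKM. Srebf1, a regulator of fat synthesis, rose from 5.54 to 50.5 FPKM and the desaturase gene Scd1 from 668 ± 288 to 3010 ± 1180. Fasn, the fatty acid synthase, rose from 5.16 to 14.1 FPKM (log2 change 1.22), but its call was lost without Null replicate 3 (1.07) or Null replicate 5 (1.05) and after quantile normalisation (0.88). Lipid droplet genes rose in 12 of 16 cases and fell in 1 (12 and 2 over the list alone; mean 1.49, adjusted p = 0.00157; adjusted p = 0.215 with an estimated correlation). The fatty acid transporter Cd36 rose from 7.97 ± 3.12 to 70.9 ± 6.67 FPKM.

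Matrix and immune cell genes rose in the Null livers. All 20 tested collagen and matrix genes rose over all genes and over the list alone, with a mean log2 change of 1.99 (adjusted p = 3.32e-12; adjusted p = 0.0831 with an estimated correlation). Col1a1, a main fibrillar collagen, rose from 0.306 ± 0.096 to 6.99 ± 2.98 FPKM, and Col1a2 from 2.63 to 46.3. Recruited and lipid-associated macrophage genes rose in 11 of 14 cases and fell in 1 (12 and 1 over the list alone; mean 2.28, adjusted p = 1.84e-06; adjusted p = 0.0964 with an estimated correlation). Lgals3, a galectin of macrophages, rose from 2.97 to 59.1 ± 9.06 FPKM, and Mmp12, a macrophage elastase, from 0.211 ± 0.123 to 40.2 ± 13.9. Interferon response genes rose in 11 of 12 cases (7 after quantile normalisation; mean 1.22, adjusted p = 0.000172; adjusted p = 0.0831 with an estimated correlation). Markers of other cell types moved in the same direction, with stellate cell genes at a mean of 1.24 (11 of 14 rose; adjusted p = 0.149 with an estimated correlation), Kupffer cell genes at 1.51 (8 of 9 rose and 1 fell; adjusted p = 0.149 with an estimated correlation) and endothelial genes at 1.15 (9 of 10 rose; adjusted p = 0.0831 with an estimated correlation). Acta2, a marker of activated stellate cells, rose from 2.36 to 8.10 FPKM (log2 change 1.42, adjusted p = 0.0134), and its call was lost after quantile normalisation (1.07) and median-ratio scaling (1.12). Cell cycle genes rose in 11 of 14 cases (12 over the list alone, 7 after quantile normalisation; mean 0.98, adjusted p = 0.00181; adjusted p = 0.0831 with an estimated correlation). Ly6d, a cell surface gene, rose from 3.15 ± 2.65 to 194 ± 61.6 FPKM (log2 change 5.75).

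Several hepatocyte programmes were lower in the Null livers. Of the 15 male-biased liver genes, 12 fell (13 over the list alone), with a mean log2 change of -2.29 (adjusted p = 2.84e-19), and this call held with an estimated correlation (adjusted p = 0.043). Mup14, a major urinary protein gene, fell from 24500 ± 8470 to 584 ± 613 FPKM, although near-identical Mup copies make the value of each single member uncertain. Periportal hepatocyte genes fell in 5 of 12 cases (8 with median-ratio scaling; mean -0.59, adjusted p = 8.53e-07; adjusted p = 0.0482 with an estimated correlation). Pck1, an enzyme of gluconeogenesis, fell from 387 to 158 ± 36.7 FPKM. Acute phase genes fell in 7 of 19 cases (11 with median-ratio scaling; mean -0.62, adjusted p = 2.59e-08; adjusted p = 0.149 with an estimated correlation), among them the fibrinogen gene Fga, from 315 to 93.9 FPKM. Chow libraries varied widely in acute phase scores (-1.236 to 1.003), and all 5 Null libraries (-0.846 to -0.322) lay within that range. General hepatocyte markers had a mean of -0.24, with 1 of 14 higher and 4 lower (adjusted p = 1.84e-06; adjusted p = 0.0831 with an estimated correlation), and this call was lost after quantile normalisation (adjusted p = 0.291). With median-ratio scaling 10 of the 14 were lower.

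In the diet comparison 3674 of 11226 genes changed (limma, adjusted p under 0.05), 3260 higher and 414 lower, and 1482 changed at least 2-fold. The median of all tested genes was 0.31 higher on the log2 scale in Null than in Chow livers, and -0.011 after quantile normalisation. The share of higher calls was 88.7% as deposited and 54.9% after quantile normalisation, where 1558 genes rose and 1279 fell and 1949 of the calls were shared. With all 25 libraries in the fit 1063 genes were called. Of the lists, 20 passed camera, and only the male-biased and periportal lists held with an estimated correlation.

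GSK against Null asks what the ileal transport inhibitor did on its own. The bile acid synthesis genes Cyp7a1 and Cyp8b1 had higher means in GSK livers, without a call. Cyp7a1 had 51.5 ± 13.6 FPKM in Null and 127 ± 34.1 in GSK livers (SD, n = 5 each; log2 difference 1.27 ± 0.48 (SE), limma adjusted p = 0.613). Cyp8b1 had 48.2 ± 22.1 and 151 ± 38.2 FPKM (log2 difference 1.75, adjusted p = 0.058). It passed the test without Null replicate 3 (1.93), Null replicate 4 (1.38), Null replicate 5 (1.89) or GSK replicate 4 (1.94), with median-ratio scaling (1.80), without the filter (1.75) and with a replicate block (1.75). In the bile acid synthesis list 0 of 15 genes passed over all genes and 2 were higher when adjusted over the list alone (mean 0.22, camera adjusted p = 0.0125; adjusted p = 0.18 with an estimated correlation; adjusted p = 0.291 after quantile normalisation).

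Collagen and matrix genes were lower in GSK than in Null livers as a list, with a mean log2 difference of -0.64 (camera adjusted p = 8.66e-12; adjusted p = 0.18 with an estimated correlation). None of the 20 members passed over all genes (0 of 20), and 9 were lower when adjusted over the list alone. Col1a1 had 6.99 ± 2.98 and 2.74 ± 0.975 FPKM (log2 difference -1.07, adjusted p = 0.374). Recruited macrophage genes had a mean of -0.61, with 0 of 14 lower over all genes and 3 over the list alone (adjusted p = 2.4e-05; adjusted p = 0.194 with an estimated correlation). Cholangiocyte genes had a mean of -0.34, with 0 of 9 lower over all genes and 2 over the list alone (adjusted p = 0.0177; adjusted p = 0.231 with an estimated correlation). Cholesterol synthesis genes had a mean of 0.30, with 1 of 22 higher over the list alone (adjusted p = 1.73e-08; adjusted p = 0.194 with an estimated correlation). Erythroid genes formed the list whose call held with an estimated correlation (mean 1.35, adjusted p = 1.53e-09; adjusted p = 0.00279 with an estimated correlation), with 4 of 4 members higher over the list alone and 0 over all genes. These members were Hbb-bs, Hbb-bt, Hba-a2 and Alas2. Globin copies may share reads, so they are not 4 separate measures. Chow libraries alone ran from -0.482 to 1.29 in the erythroid score. Hbb-bs, an adult globin gene with a near-identical copy, had 496 ± 146 and 1460 ± 533 FPKM (adjusted p = 0.218).

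For GSK against Null limma called 0 of 11226 genes, while 767 had an unadjusted p under 0.05. Quantile normalisation gave 0 genes, median-ratio scaling 1 (Cyp8b1), a fit without the filter 10 (Cyp8b1 among them) and a replicate block 1 (Cyp8b1). With all 25 libraries 0 genes were called. The count was 1 without Null replicate 3 or GSK replicate 1 and 2 without Null replicate 4, Null replicate 5 or GSK replicate 4. On simulated data 66% of genes changed by 1 on the log2 scale were recovered in this comparison. That simulation held many changed genes at higher Null levels, so it may overstate recovery in a comparison that called 0 genes. 12 of 30 tested lists passed camera, of which the erythroid list held with an estimated correlation.

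**Figure D1:**
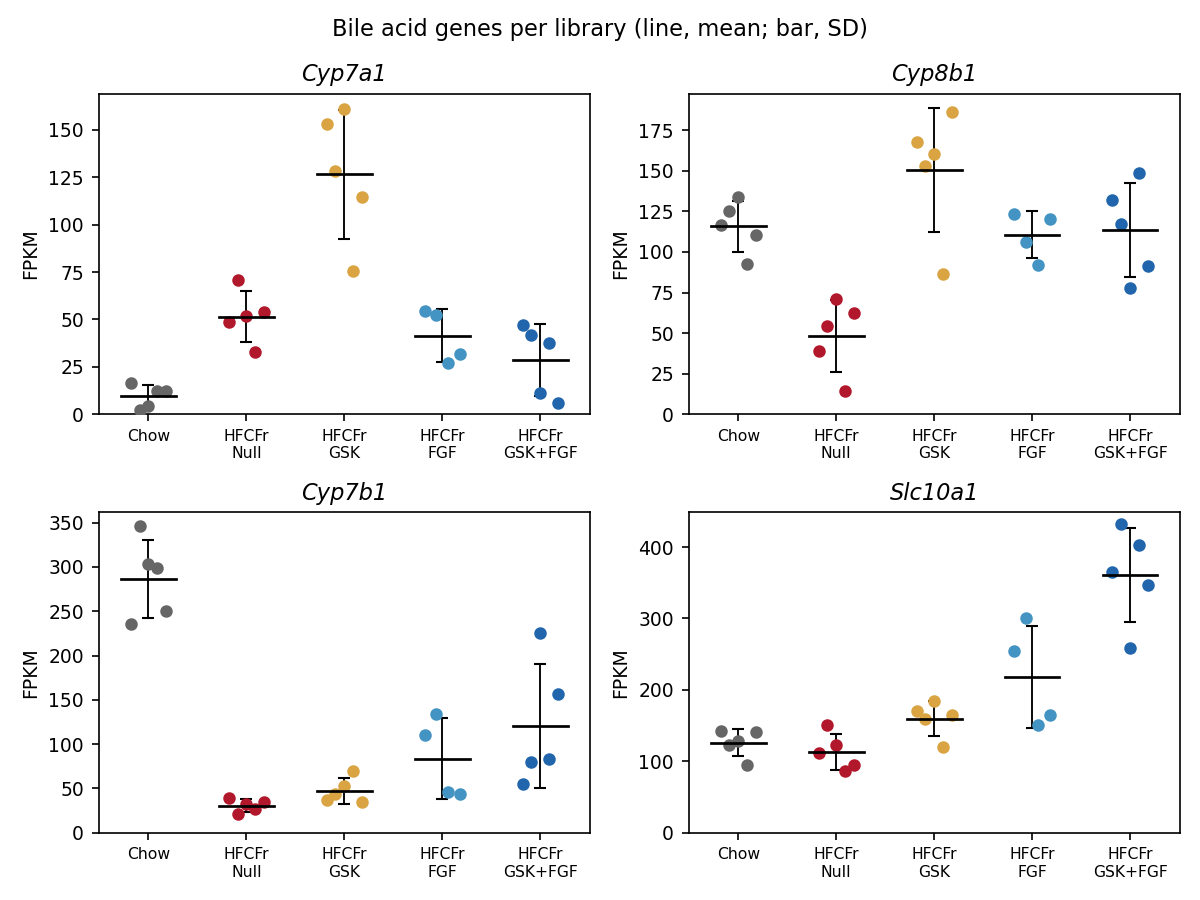
Deposited FPKM of the bile acid genes Cyp7a1, Cyp8b1, Cyp7b1 and Slc10a1 in each library, by group; each point is a library, the line the group mean and the bar the SD. Slc10a1 averaged 113 FPKM in Null and 361 in combination livers, and Cyp7a1 127 in GSK and 28.6 in combination livers.

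FGF against Null asks what FGF15 from hepatocytes did on its own (n = 4 against 5). The fixed list of FGF signalling response genes, with 9 tested members, had no higher mean in FGF livers. Its mean log2 change was -0.29, and -0.10 after quantile normalisation, where 1 member was higher and 0 were lower. Its score was 0.86 ± 0.13 in Null, 0.56 ± 0.19 in FGF and 0.48 ± 0.13 in combination livers (SD). The uptake transporter gene Slc10a1 rose from 113 ± 25.4 to 218 ± 71.8 FPKM (log2 change 0.91 ± 0.20 (SE), limma adjusted p = 0.0381). Cyp8b1 rose from 48.2 ± 22.1 to 111 ± 14.4 FPKM (log2 change 1.35, adjusted p = 0.0397), while Cyp7a1 had 51.5 and 41.4 ± 14.0 FPKM without a call (adjusted p = 0.795). Male-biased genes rose in 3 of 15 cases (8 over the list alone; mean 1.08, adjusted p = 8.73e-14; adjusted p = 0.0617 with an estimated correlation). Sult2a8, a sulfotransferase gene of male liver, rose from 34.7 ± 9.38 to 185 ± 110 FPKM, and Mup3 from 3600 to 11800. Collagen and matrix genes fell in 6 of 20 cases (17 over the list alone; mean -0.93, adjusted p = 6.65e-11; adjusted p = 0.129 with an estimated correlation), and in 1 case after quantile normalisation. Col1a1 fell to 2.47 ± 1.94 FPKM (log2 change -1.33, adjusted p = 0.0417). Macrophage genes fell in 4 of 14 cases (12 over the list alone; mean -1.14, adjusted p = 2.02e-07; adjusted p = 0.121 with an estimated correlation), among them Lgals3, from 59.1 to 23.7 ± 19.8 FPKM. Cholangiocyte genes had a mean of -0.90, with 1 of 9 lower and 4 over the list alone (adjusted p = 0.00389; adjusted p = 0.159 with an estimated correlation). Lpl, the lipoprotein lipase, fell from 41.0 ± 4.96 to 15.9 ± 12.5 FPKM (log2 change -1.68, adjusted p = 0.0317). Cholesterol synthesis genes had a mean of -0.05 while camera placed the list upward (adjusted p = 0.0445), and this call was lost with an estimated correlation (adjusted p = 0.577). Each gene call given here was lost without Null replicate 4, FGF replicate 2 or FGF replicate 3, and those of Col1a1 (-1.15) and Mup3 (0.95) after quantile normalisation. Without these 3 libraries in turn Slc10a1 had 0.82, 0.82 and 0.74 and Col1a1 -1.46, -1.27 and -0.94. All but that of Sult2a8 were also lost without Null replicate 1 (Cyp8b1 1.32, Lpl -1.65) or Null replicate 2 (Cyp8b1 1.43, Lpl -1.68). Those of Lgals3 (-1.74 and -1.77) and Col1a1 (-1.32 and -1.38) were lost without Null replicate 3 or Null replicate 5, and that of Slc10a1 without Null replicate 5 (0.85).

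Of 11226 genes, 119 changed between FGF and Null livers (24 higher, 95 lower; limma). The median of all genes was -0.16 and 0.018 after quantile normalisation, which called 88 genes (37 higher, 51 lower; 42% higher against 20.2% as deposited), 62 of them shared. These calls rest on single libraries. The count was 0 without Null replicate 4, FGF replicate 2 or FGF replicate 3. It was 4 without Null replicate 2, 6 without Null replicate 1, 66 without Null replicate 3, 383 without FGF replicate 4 and 376 without FGF replicate 5. The fit of the compared groups alone gave 0 genes, a pseudocount of 0.1 gave 2 and the fit without the filter 51. With all 25 libraries 91 genes were called, all of them lower. 19 lists passed camera and none held with an estimated correlation.

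The combination against Null asks what both treatments did together. Cholesterol synthesis genes rose in 13 of 22 cases (16 over the list alone), with a mean log2 change of 0.94 (adjusted p = 2.04e-24), and the call held with an estimated correlation (adjusted p = 0.0196). Cyp51 rose from 8.20 ± 2.09 to 37.8 ± 8.67 FPKM (SD, n = 5 each; log2 change 2.07 ± 0.25 (SE), limma adjusted p = 3.28e-05). Nsdhl, another enzyme of sterol synthesis, rose from 2.77 ± 1.22 to 13.6 ± 3.56 FPKM. Slc10a1 rose from 113 ± 25.4 to 361 ± 66.1 FPKM (log2 change 1.67, adjusted p = 2.83e-05) and Slco1a1, an organic anion transporter of male liver, from 8.17 ± 7.15 to 145 ± 45.7. Cyp8b1 rose to 113 ± 28.9 FPKM (log2 change 1.35, adjusted p = 0.00379) and Cyp7b1 to 120 ± 70.0 (log2 change 1.78, adjusted p = 0.00112). Cyp7a1 had 51.5 ± 13.6 and 28.6 ± 18.8 FPKM without a call (adjusted p = 0.111). In the bile acid synthesis list 3 of 15 genes rose and 1 fell, with a mean of 0.12 and a median of -0.14, and its call (adjusted p = 0.0337) was lost with an estimated correlation (adjusted p = 0.153).

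Matrix and macrophage genes fell in the combination group. Collagen and matrix genes fell in 17 of 20 cases (19 over the list alone), with a mean log2 change of -1.47 (adjusted p = 5.46e-14; adjusted p = 0.0887 with an estimated correlation). Col1a1 fell from 6.99 ± 2.98 to 0.437 ± 0.301 FPKM (log2 change -2.43, adjusted p = 3.22e-05) and Col3a1 from 36.7 ± 8.99 to 3.59 ± 0.863. Macrophage genes fell in 11 of 14 cases (11 lower and 1 higher over the list alone; mean -1.69, adjusted p = 3.19e-08; adjusted p = 0.0887 with an estimated correlation). Mmp12 fell from 40.2 ± 13.9 to 2.39 ± 1.26 FPKM and Lpl from 41.0 ± 4.96 to 3.28 in 5 livers each. Genes of the NRF2 oxidative stress response fell in 10 of 13 cases (12 lower and 1 higher over the list alone; mean -1.44, adjusted p = 1.04e-06; adjusted p = 0.105 with an estimated correlation). Gsta1, a glutathione transferase, fell from 13.4 ± 4.87 to 0.239 FPKM. Lipid droplet genes fell in 9 of 16 cases (mean -0.95, adjusted p = 0.00192; adjusted p = 0.292 with an estimated correlation), among them Cidec, from 33.5 to 7.44 FPKM, and in 5 cases after quantile normalisation. Among markers of other cell types the cholangiocyte list was lower, with a mean of -1.11 (3 of 9 fell, 7 over the list alone; adjusted p = 0.00318; adjusted p = 0.153 with an estimated correlation). Kupffer cell genes had a mean of -0.60 (4 of 9 fell; camera adjusted p = 0.0646) and stellate cell genes -0.41 (4 of 14 fell; camera adjusted p = 0.688), without a list call. Endothelial genes (mean -0.25), B and plasma cell genes (-0.08) and erythroid genes (-0.11) had no list call either, and the B and plasma cell mean turned to 0.12 after quantile normalisation and the erythroid mean to 0.13 with median-ratio scaling. After quantile normalisation 1 cholangiocyte, 2 Kupffer cell and 2 stellate cell genes were lower, and 1 stellate cell gene was higher. Acta2 fell from 8.10 to 2.16 FPKM (log2 change -1.49, adjusted p = 0.0223). Its call was lost without Null replicate 4 (-1.31), Null replicate 5 (-1.31), combination replicate 2 (-1.38) or combination replicate 5 (-1.34) and after quantile normalisation (-1.22).

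Some hepatocyte programmes rose in the combination group, while acute phase genes were lower still, with 7 of 19 lower than in Null livers (4 after quantile normalisation; mean -0.78, camera adjusted p = 0.238). Pericentral hepatocyte genes rose in 5 of 13 cases (6 over the list alone; mean 0.60, adjusted p = 4.3e-11; adjusted p = 0.0131 with an estimated correlation), among them the cytochrome gene Cyp1a2, from 135 to 295 FPKM. Male-biased genes rose in 7 of 15 cases (8 higher and 1 lower over the list alone; mean 1.40, adjusted p = 5.46e-14; adjusted p = 0.0497 with an estimated correlation). Hsd3b5, a steroid dehydrogenase of male liver, rose from 0.108 to 15.7 FPKM. General hepatocyte markers rose in 5 of 14 cases and fell in 1 (mean 0.26, adjusted p = 1.86e-08; adjusted p = 0.0497 with an estimated correlation; adjusted p = 0.218 after quantile normalisation, with 3 higher and 1 lower, and 9 higher with median-ratio scaling). Cell cycle genes fell in 8 of 14 cases (11 over the list alone; mean -0.85, adjusted p = 9.6e-05; adjusted p = 0.0497 with an estimated correlation), among them the proliferation marker Mki67, from 2.33 to 0.58 FPKM. After quantile normalisation 3 of the 14 passed and with median-ratio scaling 4. Srebf1 fell from 50.5 ± 8.04 to 24.4 ± 7.43 FPKM (log2 change -1.06, adjusted p = 0.0223), and its call was lost without combination replicate 3 (-0.94) or combination replicate 5 (-0.96) and after quantile normalisation (-0.90). Scd1 had 3010 and 1820 FPKM without a call (adjusted p = 0.152).

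Between combination and Null livers 1640 genes changed, 228 higher and 1412 lower, and 557 changed at least 2-fold (limma). The median of all genes was -0.21 and 0.022 after quantile normalisation, which called 1010 genes (426 higher, 584 lower), 787 of them shared, and moved the share of higher calls from 13.9% to 42.2%. The count was 1056 without combination replicate 3, and 189 with all 25 libraries. Of 17 lists passing camera, the cholesterol synthesis, male-biased, pericentral, hepatocyte and cell cycle lists held with an estimated correlation.

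**Figure D2:**
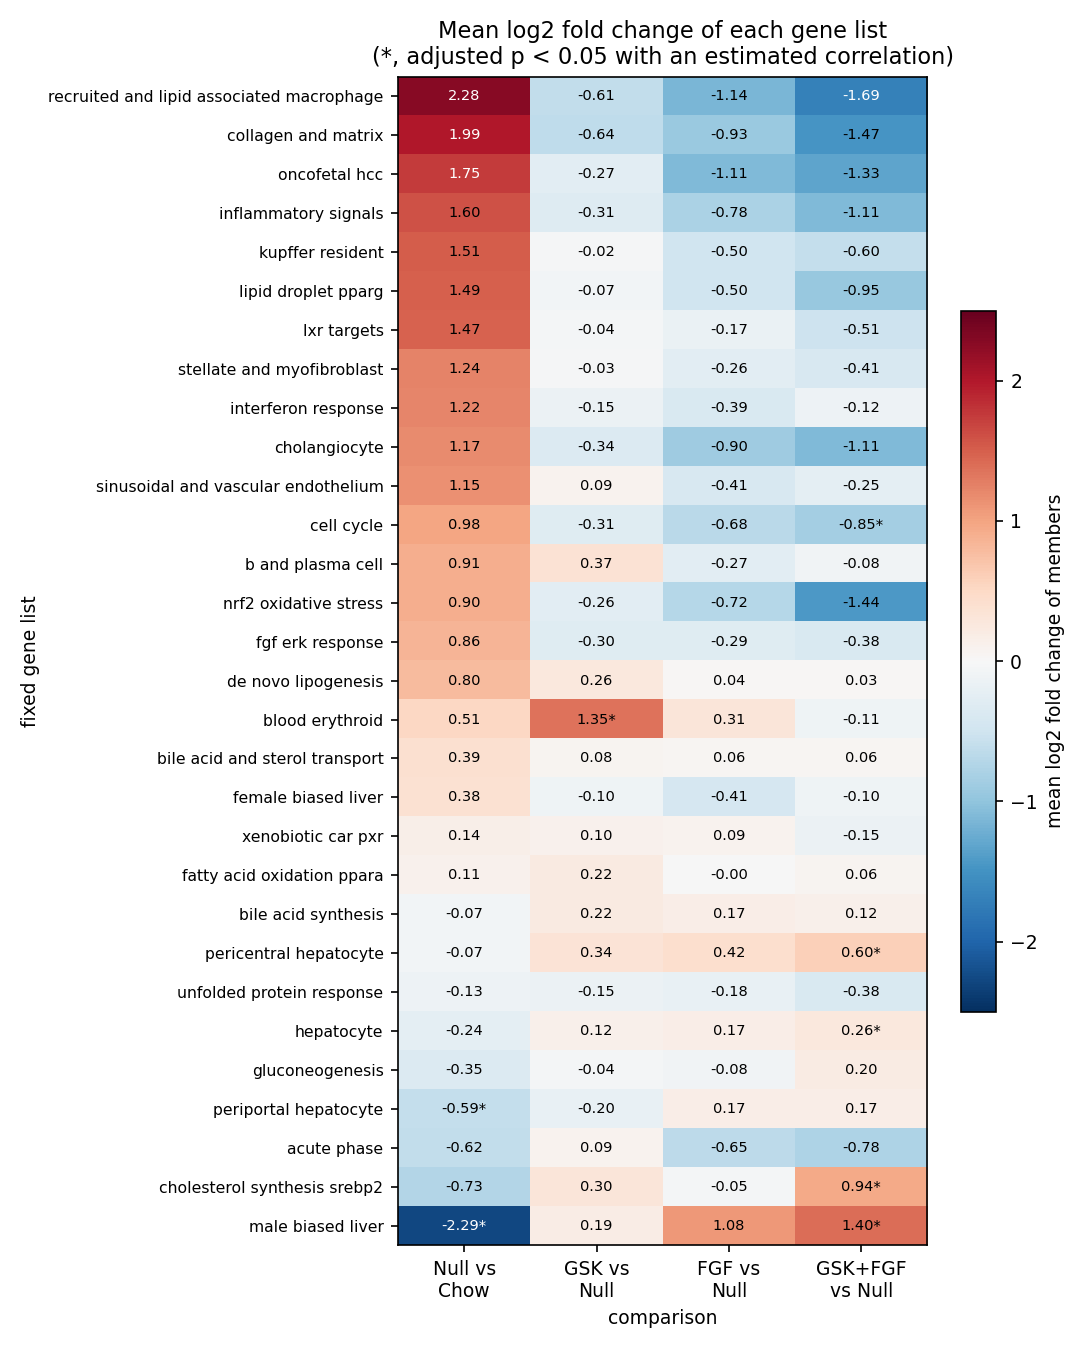
Mean log2 change of the tested members of 30 gene lists in the comparisons of Null with Chow and of each treated group with Null; colour gives the mean and a star marks an adjusted p under 0.05 with an estimated correlation. Collagen and matrix genes averaged 1.99 with the diet, -0.64 with GSK, -0.93 with FGF and -1.47 with the combination.

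The treated groups were compared with each other to ask what each agent added to the other. Adding FGF15 to the inhibitor (combination against GSK) changed 545 genes, 87 higher and 458 lower (limma). Csad, an enzyme of the synthesis of taurine, with which bile acids are conjugated, fell from 139 ± 38.2 to 11.1 ± 5.22 FPKM (SD, n = 5 each; log2 change -3.57 ± 0.32 (SE), adjusted p = 1.41e-06). Hamp, which encodes the iron hormone hepcidin, rose from 8.15 ± 10.1 to 48.1 ± 26.6 FPKM (log2 change 3.36, adjusted p = 0.00691), and its call was lost in a fit of the compared groups alone. Macrophage genes fell in 8 of 14 cases (mean -1.08; adjusted p = 0.215 with an estimated correlation) and collagen and matrix genes in 8 of 20 (10 over the list alone; mean -0.83, adjusted p = 2.27e-06; adjusted p = 0.243 with an estimated correlation). Cholesterol synthesis genes rose in 7 of 22 cases (11 higher and 1 lower over the list alone; mean 0.65; adjusted p = 0.0666 with an estimated correlation). Erythroid genes fell in 3 of 4 cases (4 over the list alone; mean -1.46, adjusted p = 0.000392; adjusted p = 0.0666 with an estimated correlation). Quantile normalisation called 363 genes, 288 of them shared, with 43.8% higher against 16% as deposited. The count was 354 without GSK replicate 5, 272 without combination replicate 3, 288 without combination replicate 5 and 13 with all 25 libraries.

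Adding the inhibitor to FGF15 (combination against FGF, n = 5 against 4) raised 6 genes and lowered 0, while 747 genes had an unadjusted p under 0.05 (limma). Of 100 groupings of these libraries, the real one included, 7 gave at least 6 genes, so chance cannot be excluded for this count. 4 of the 6 called genes belong to sterol synthesis. Cyp51 rose from 7.92 ± 2.06 to 37.8 ± 8.67 FPKM (log2 change 2.11 ± 0.27 (SE), adjusted p = 0.000369), Nsdhl by 2.11 (adjusted p = 0.000309), Hsd17b7 by 1.16 (adjusted p = 0.00856) and Msmo1 by 1.81 (adjusted p = 0.0178). Cyp17a1, a steroid hydroxylase, rose from 3.17 to 35.3 FPKM (log2 change 3.02, adjusted p = 0.00856), and Rdh11, a retinol dehydrogenase, by 1.55 (adjusted p = 0.00198). In the cholesterol synthesis list 4 of 22 genes rose over all genes and 16 over the list alone (mean 1.00, adjusted p = 1.47e-36), and the call held with an estimated correlation (adjusted p = 0.00558). The call of Cyp17a1 was lost with a pseudocount of 0.1 (3.34) and that of Rdh11 in a fit of the compared groups alone. The call of Msmo1 was lost without FGF replicate 2 (1.83), FGF replicate 4 (1.81), combination replicate 2 (1.81) or combination replicate 4 (1.78). The count of genes was 43 without FGF replicate 3 (9 higher, 34 lower), so most calls were then lower. It was 10 without combination replicate 1 (6 higher, 4 lower) and 12 without combination replicate 3 (11 higher, 1 lower). Quantile normalisation called 7 genes, with all 6 shared. With all 25 libraries 4 genes were called.

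Between FGF and GSK livers (n = 4 against 5) 4 genes differed, all lower with FGF, and 1139 had an unadjusted p under 0.05 (limma). Csad had 139 FPKM in GSK and 33.1 in FGF livers (log2 change -2.21, adjusted p = 0.0156), but its call was lost without GSK replicate 2 (-2.22), GSK replicate 5 (-2.12), FGF replicate 2 (-2.05) or FGF replicate 3 (-1.84). The others were the immunoglobulin gene Ighm (-1.78), Golga7 (-1.75) and Fam193b (-0.84), whose calls were lost after quantile normalisation. The call of Fam193b was lost without any 1 library (-0.90 to -0.79) and that of Golga7 without any but GSK replicate 1 (-1.87 to -1.65). That of Ighm was lost without GSK replicate 2 (-1.51), GSK replicate 5 (-1.77), FGF replicate 2 (-1.53), FGF replicate 3 (-1.83) or FGF replicate 5 (-1.73). The count was 0 without GSK replicate 2, GSK replicate 5, FGF replicate 2 or FGF replicate 3, 2 without GSK replicate 3 or FGF replicate 5 and 7 without FGF replicate 4. Male-biased genes had a mean of 0.89, with 0 of 15 passing over all genes and 4 higher over the list alone (camera adjusted p = 3.42e-13; adjusted p = 0.0928 with an estimated correlation). The interaction, which asks whether the inhibitor acted differently with FGF15 than without, gave 0 genes by limma, with 516 at an unadjusted p under 0.05. Quantile normalisation, median-ratio scaling and the fit of all 25 libraries also gave 0, and the fit of the compared groups alone gave 2. The interaction count was 1 without Null replicate 1, 2 without GSK replicate 2, 2 without FGF replicate 3 and 3 without combination replicate 3.

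The combination group was set against Chow to ask how far treated livers remained from livers on chow, with the vector again in the treated mice alone as far as the labels say (n = 5 each). Collagen and matrix genes stayed higher in 3 of 20 cases (mean 0.53, adjusted p = 0.012; adjusted p = 0.673 with an estimated correlation) and macrophage genes in 4 of 14 (5 over the list alone; mean 0.59, adjusted p = 0.0448; adjusted p = 0.632 with an estimated correlation). Male-biased genes stayed lower in 5 of 15 cases (8 over the list alone; mean -0.89, adjusted p = 2.61e-06; adjusted p = 0.155 with an estimated correlation). NRF2 response genes were higher in 1 and lower in 5 of 13 cases (mean -0.54, adjusted p = 0.000233; adjusted p = 0.207 with an estimated correlation). Calls that held with an estimated correlation were those of the interferon list (10 of 12 higher, 11 over the list alone; mean 1.10, adjusted p = 5.73e-08; adjusted p = 0.0194 with an estimated correlation), the endothelial list (6 of 10 higher, 8 over the list alone; mean 0.91, adjusted p = 0.0499 with an estimated correlation) and the unfolded protein response list (5 of 15 lower; mean -0.51, adjusted p = 0.0194 with an estimated correlation). Cyp3a11, a drug-metabolising cytochrome, was at 1710 FPKM in Chow and 221 in combination livers (log2 change -2.95, limma adjusted p = 0.000126), and Csad at 131 and 11.1. Psmb9, an immunoproteasome subunit, differed by a log2 change of 2.63 (151 FPKM in combination livers). In all 1332 genes differed, 997 higher and 335 lower. The median of all genes was 0.10 higher, and quantile normalisation called 1266 genes, 1064 of them shared, with 58.5% higher against 74.8% as deposited. With all 25 libraries 30 genes were called, and 779 in a fit of the compared groups alone.

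**Figure D3:**
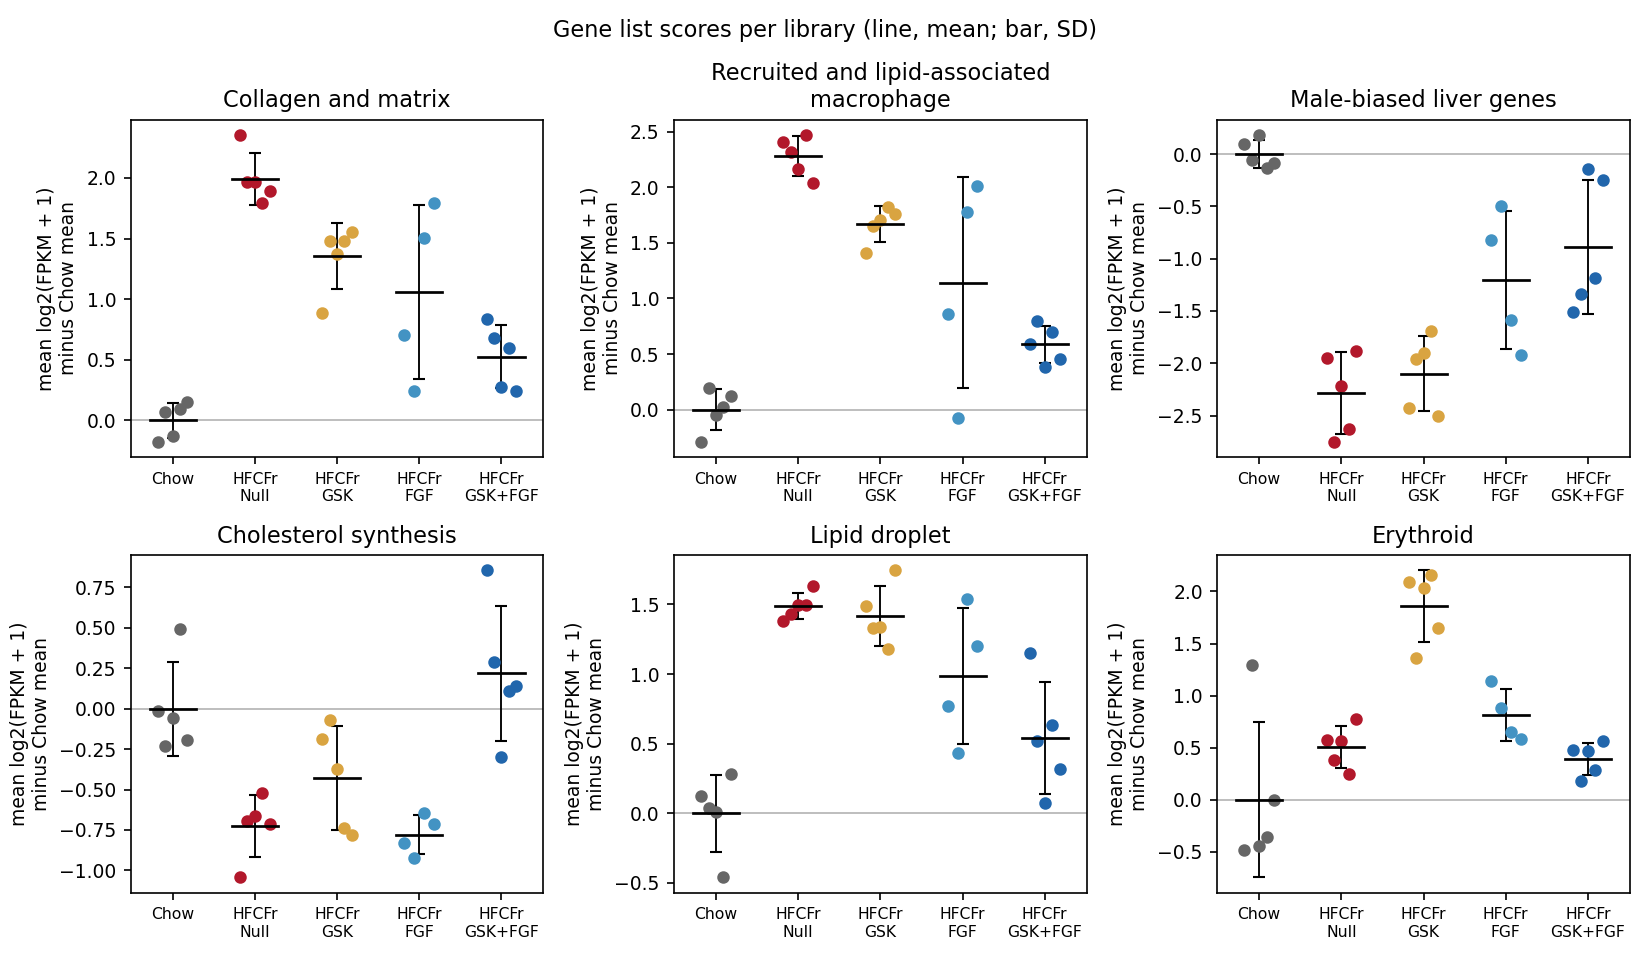
Score of 6 gene lists in each library, by group, as the mean log2(FPKM + 1) of the members minus the mean of the Chow libraries; each point is a library. Macrophage scores averaged 2.28 in Null, 1.67 in GSK, 1.14 in FGF and 0.59 in combination livers, and erythroid scores 1.86 in GSK and 0.39 in combination livers.

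Collagen and matrix scores were 1.99 ± 0.21 in Null (SD, n = 5), 1.35 ± 0.27 in GSK (n = 5), 1.06 ± 0.72 in FGF (n = 4) and 0.53 ± 0.26 in combination livers (n = 5). Male-biased scores were -2.29 ± 0.39, -2.10 ± 0.35, -1.21 ± 0.66 and -0.89 ± 0.64 in the same order. Cholesterol synthesis scores were -0.73 ± 0.19, -0.43 ± 0.32, -0.78 ± 0.12 and 0.22 ± 0.42. To measure reversal without shared controls, diet-changed genes were called with part of the Null libraries and the treatment change was taken against the rest, over 20 divisions with a median of 2531 genes. With GSK 69.1% of these genes moved back toward Chow, below the 95th percentile of unchanged simulated groups (72.9%, median 45%). Each simulated value came from a single division on a fixed set of genes, while the real value is a median over 20. The comparison therefore does not decide whether the GSK share exceeds chance. With all Null libraries on both sides the GSK share was 74.6%, and the 95th percentile simulated for that version was 72.6%. That simulation kept the genes called in the real fit and did not call them anew in each draw. It therefore leaves out part of the effect of sharing the Null libraries, and this version does not decide about chance either. With FGF 81.3% moved back (simulated 95th percentile 71.3%) and with the combination 87.9% (72.2%). Single divisions gave 72.0 to 86.0% with FGF and 80.4 to 91.4% with the combination. These simulations had the same limits as those for GSK. They also drew their spread from all 24 libraries, while the FGF libraries varied more (collagen score SD 0.72), so the FGF percentile may be too low. The slope of the treatment change on the diet change, per library, was -0.12 ± 0.05 with GSK (n = 5), -0.31 ± 0.22 with FGF (n = 4) and -0.48 ± 0.14 with the combination (n = 5). GSK and combination slopes differed (exact two-sided permutation p = 0.00794, adjusted p = 0.0238 over 3 comparisons). GSK and FGF slopes (exact permutation p = 0.0952, adjusted p = 0.143) and FGF and combination slopes (exact permutation p = 0.214, adjusted p = 0.214) were not shown to differ.

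**Figure D4:**
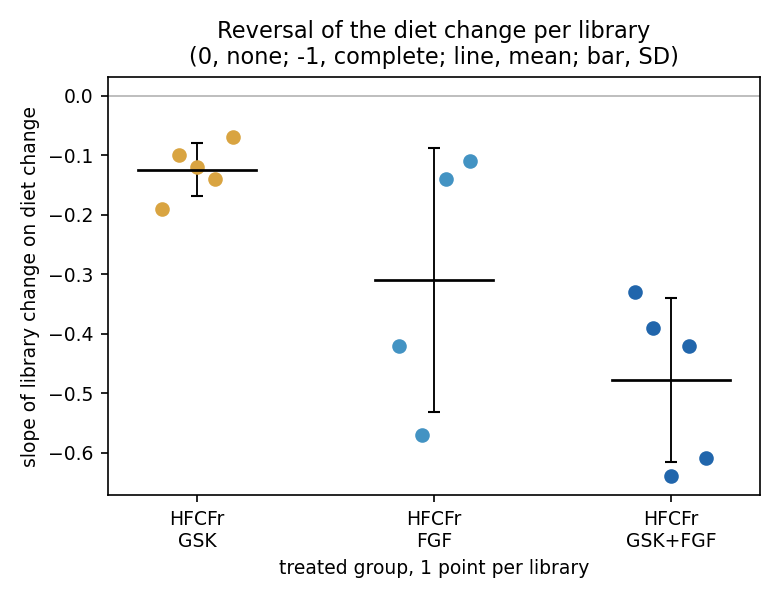
Slope of the treatment change on the diet change across diet-changed genes, for each library of the 3 treated groups; a slope of 0 is no reversal and -1 would be full reversal. Slopes ranged from -0.19 to -0.07 with GSK, -0.57 to -0.11 with FGF and -0.64 to -0.33 with the combination.

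Responses to GSK and to FGF were compared across genes, which are not independent replicates. Their correlation was 0.48, the same as the 0.48 that shared Null libraries gave in simulated unchanged groups, and with Null libraries divided between both sides it was 0.13 (0.01 to 0.22). The covariance was 0.065 against 0.051 in the simulation. No overlap of called genes could be had, since GSK against Null called 0 genes. GSK and combination responses correlated at 0.50 (simulated 0.52, divided 0.18), with a covariance of 0.082 against 0.052. FGF and combination responses correlated at 0.74 (simulated 0.48, divided 0.45), with a covariance of 0.155 against 0.05. They shared 24 higher and 90 lower genes, where independent calls would share 0.49 and 11.95. Because both comparisons use the same Null libraries, more overlap than that is given by the design alone, and the overlap without a shared response was not simulated.

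Several genes of interest were too low to test. Fgf15 had at most 0.798 FPKM in any library, and where the vector's transcript ends is unknown, so this value says nothing about vector expression. Nr0b2, a bile acid responsive repressor, had means of 0.098 FPKM in Null and 0.299 in GSK livers. The chemokine gene Ccl2 had 1.23 ± 1.38 FPKM in Null and 0.323 in combination livers, and the macrophage gene Adgre1 0.0219 and 0.0609.

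The genes given most room are protein-coding in GENCODE M21 on GRCm38 (mm10). Cyp7a1 (ENSMUSG00000028240) lies on chromosome 4 from 6265612 to 6275633. Cyp8b1 (ENSMUSG00000050445) lies on chromosome 9 from 121914356 to 121916305. Cyp7b1 (ENSMUSG00000039519) lies on chromosome 3 from 18071950 to 18243338. Slc10a1 (ENSMUSG00000021135) is on chromosome 12 from 80953183 to 80968705. Col1a1 (ENSMUSG00000001506) is on chromosome 11 from 94936224 to 94953042. Lpl (ENSMUSG00000015568) is on chromosome 8 from 68880491 to 68907448. Cyp51 (ENSMUSG00000001467) is on chromosome 5 from 4081145 to 4104746. Mmp12 is on chromosome 9 from 7344381 to 7369499 and Csad on chromosome 15 from 102176999 to 102204724. Slco1a1 is on chromosome 6 from 141907282 to 141946962 and Hamp on chromosome 7 from 30942368 to 30944032.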

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

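All the tests of explanations in this part were chosen after the result was seen, while the comparisons with other groupings of the libraries were planned before. Single libraries that stood far from the rest of their group were found in 14 of 232 groups of values, where chance gives about 1 in 20, or 11.6. Differences between the effects of the groups were tested by the interaction and by exact permutation.

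Most genes called with the diet were higher. The median log2 difference of the Null libraries from Chow was 0.31 ± 0.04 (SD, n = 5), while the 200 most abundant genes took 73.3% of FPKM in Chow and 64.7% in Null livers, and 21 Mup genes alone took 24.9 ± 5.43% and 8.82 ± 2.49%. Scaling each library to its total without those 200 genes left a median of 0.13 ± 0.02, so a smaller share of these genes could be part of the pattern. This SD covers the Null libraries alone and leaves out the spread of the Chow libraries. Whether the smaller share is the whole cause is therefore not decided. A lower share of hepatocyte RNA would raise markers of every other cell type alike. Macrophage and erythroid scores in Null livers lay 1.77 ± 0.37 apart, but they were picked as the highest and lowest of 7 lists. The other lists averaged 0.91 to 1.51, and the erythroid score had an outlying Chow library (1.29, others -0.482 to -0.006). The gap therefore does not decide about this simple form. A diet, or vector, that raised many genes, or brought in some cell types more than others, stays open and was not tested separately.

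Clock genes, a list fixed only after their values were seen, differed between Chow and Null livers. Of 14 tested genes 9 changed (limma), with Per2 (log2 change 2.06), Per3 (1.99) and Usp2 (2.97) among 8 that rose and Nfil3 (-1.71) the one that fell. After quantile normalisation 7 changed, of which 6 were among those 9 (5 higher and 1 lower), which argues against scaling as the whole cause. Over 42 tests in the 3 comparisons of treated with Null livers limma called 0, with 2 at an unadjusted p under 0.05. Chow and diet mice killed at different times of day and a rhythm changed by the diet or by the vector cannot be told apart. Diet and any difference in time would coincide, and the labels used give no time. This limit covers every gene in the comparisons of Null and combination livers with Chow. Cyp7a1, which also follows the clock, is only an example of a gene that may be affected.

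The 4 FGF libraries lay far apart, with a macrophage score SD of 0.95 against 0.16 to 0.19 in the other groups. A combination library labelled as FGF is argued against, because the highest cholesterol synthesis score among FGF libraries was -0.64 and the lowest of the combination group was -0.30. A chow library labelled as FGF is argued against by Per2, which had at least 3.31 FPKM in the FGF libraries and at most 1.65 in Chow. A Null or GSK library labelled as FGF was not tested. FGF replicates 4 and 5 lay at 18.9 and 21.6 on the first principal component, within the GSK range of 18.1 to 27.4. Unequal delivery of the vector between mice may contribute but cannot be told apart from other differences between mice, since Fgf15 reached only 0.798 FPKM in any library and the end of the vector's transcript is unknown. Depth also stays open within this group (1950000 to 2690000 estimated reads), with only 4 libraries to set it against.

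Several lists had a nonzero interaction in camera, and of these the erythroid list held with an estimated correlation. The erythroid interaction was -1.771 on the log2 scale (camera adjusted p = 2.21e-08, and 0.00572 with an estimated correlation). Over the list alone 4 of 4 members were lower, although near-identical globin copies among them may share reads. Cholesterol synthesis genes had an interaction of 0.699 (adjusted p = 1.84e-09; adjusted p = 0.351 with an estimated correlation). NRF2 genes had -0.467 (adjusted p = 0.00211; adjusted p = 0.48 with an estimated correlation) and interferon genes 0.413 (adjusted p = 0.00438; adjusted p = 0.351 with an estimated correlation). Lipid droplet genes had -0.376 (adjusted p = 0.0268; adjusted p = 0.624 with an estimated correlation) and LXR targets -0.305 (adjusted p = 0.0253; adjusted p = 0.48 with an estimated correlation). Bile acid synthesis genes had -0.269 (adjusted p = 0.0384; adjusted p = 0.351 with an estimated correlation) and fatty acid oxidation genes -0.155 (adjusted p = 0.0237; adjusted p = 0.624 with an estimated correlation). The reversal slopes of GSK and combination livers differed by an exact permutation p of 0.00794.

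Genes above 0 numbered 14222 in Chow replicate 5, against 13255 to 13426 in the other Chow libraries. GSK replicate 1 had 13823, against 14486 to 14586, and FGF replicate 1 had 169, against 13596 to 14291. Cyp8b1 was at 86.1 FPKM in GSK replicate 4, against 153 to 186 in the other GSK libraries. Srebf1 was at 36.7 FPKM in Null replicate 1 (others 51.8 to 57.7) and at 20.0 in GSK replicate 4 (others 55.1 to 81.3). The NRF2 score was 0.996 in GSK replicate 5 (others 0.485 to 0.632) and the collagen score 0.885 in GSK replicate 1 (others 1.375 to 1.555). Acute phase scores were -1.642 in FGF replicate 3 (others -1.17 to -1.107) and -1.13 in combination replicate 5 (others -1.529 to -1.422). The hepatocyte score was -0.235 in FGF replicate 4 (others -0.023 to 0.004). Cholangiocyte scores were 0.444 in Chow replicate 3 (others -0.236 to -0.066) and 1.736 in Null replicate 4 (others 0.979 to 1.088). The erythroid score was 1.29 in Chow replicate 2 (others -0.482 to -0.006).

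Each comparison was set against 100 groupings of its own libraries, the real one included. Only the real grouping reached the gene counts of Null against Chow (3674, highest other 594) and the combination against Null (1640, highest other 3). The same held for the combination against GSK (545, highest other 75) and against Chow (1332, highest other 245). This argues against chance for these counts, although 1 in 100 is the smallest share possible here and is not adjusted over the comparisons. For FGF against Null (119, highest other 2) also only the real grouping reached the count. That count was 0 without Null replicate 4, FGF replicate 2 or FGF replicate 3, and 0 in a fit of the compared groups alone. It rests on those libraries and on the spread shared by all groups, so chance is not taken as excluded for it. For FGF against GSK 3 of 100 groupings reached the real count of 4, 2 of them with more genes (highest other 6). That share is under the limit of 0.05 set in advance, but it is not adjusted over the comparisons, and other groupings gave more genes. Chance is therefore not taken as excluded here. The count was also 0 without GSK replicate 2, GSK replicate 5, FGF replicate 2 or FGF replicate 3. Chance cannot be excluded for the combination against FGF, where 7 groupings reached 6 genes and the highest other gave 57. A count several times the real one may come from a structure of the samples, such as the spread of the FGF libraries, or from genes that vary together, and neither was tested. For GSK against Null and for the interaction the real count was 0, which all 100 groupings reach by construction, so nothing is decided about chance. The highest other was 2 for the interaction and 55 for GSK against Null, where the same remark holds. For the number of lists passing camera, chance cannot be excluded for Null against Chow (20, highest other 23, 7 groupings). Nor can it be for GSK (12, highest other 15, 5 groupings) or the combination (17, highest other 20, 5 groupings). For FGF only the real grouping reached the number of lists (19, highest other 17). That share is not adjusted, and none of these lists held with an estimated correlation. Chance is therefore not taken as excluded for the FGF lists either.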

How the results depend on the processing

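Median-ratio scaling was chosen after the data were seen. The fit with all 25 libraries was planned as the main fit and became an alternative after the data were seen. The other tests were planned as alternatives. Except where a fit had fewer libraries or groups, the cause was not tested. Of the called named genes, 19 kept their direction and lost their call after quantile normalisation, 11 after median-ratio scaling, 26 without the filter, 26 with a pseudocount of 0.1, 13 with a replicate block, 33 in fits of the compared groups alone and 82 with all 25 libraries, apart from the reversed genes. Of 76 list calls in the diet comparison, the comparisons of each treatment with Null and the interaction, 9 held with an estimated correlation and 41 with fry. Quantile normalisation lost 17 of these list calls, the fit without the filter 5 and median-ratio scaling 3. Fits of the compared groups alone lost 3, a pseudocount of 0.1 lost 1, a replicate block 1 and all 25 libraries 16, apart from the reversed lists. Changes under about 1 on the log2 scale were often missed at this depth and number of mice.

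With all 25 libraries the counts were 1063 (Null against Chow), 189 (combination against Null), 13 (combination against GSK), 1 (FGF against GSK) and 30 (combination against Chow). In that fit FGF against Null reversed Mup19 (-0.04), Cyp8b1 (-0.01), Slc10a1 (-0.63), Mup3 (-1.07) and Nudt7 (-0.12), and the interaction of bile acid synthesis and of fatty acid oxidation genes reversed (adjusted p = 0.794 for both), since a near-empty library was averaged in. Quantile normalisation gave 1010 (combination against Null), 363 (combination against GSK) and 1 (FGF against GSK), and Serpina1b in the combination against Null reversed (-0.33). Median-ratio scaling gave 1 for GSK against Null and 1 for FGF against GSK. Without the filter GSK against Null gave 10, FGF against Null 51 and FGF against GSK 0. A pseudocount of 0.1 gave 2 for FGF against Null. With a replicate block GSK against Null gave 1 and FGF against GSK 0. In fits of the compared groups alone FGF against Null gave 0, FGF against GSK 1, the interaction 2 and the combination against Chow 779.

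The share moved back with GSK was 74.6% with all Null libraries on both sides and 72.8% for genes changed at least 2-fold by the diet. The 95th percentile simulated with all Null libraries on both sides was 72.6%. It does not decide about chance, because genes were not called anew in each draw. The share was 85.2% with FGF when all Null libraries were on both sides and 84.7% with the combination after quantile normalisation. The correlation of GSK and FGF responses was 0.13 with divided Null libraries. Leaving out 1 library at a time gave 3181 to 3674 genes (Null against Chow), 0 to 2 (GSK against Null), 0 to 383 (FGF against Null), 1056 to 1693 (combination against Null), 272 to 664 (combination against GSK), 5 to 43 (combination against FGF), 0 to 7 (FGF against GSK), 0 to 3 (interaction) and 898 to 1374 (combination against Chow). The share moved back was 64.6 to 71.0% with GSK, 75.8 to 83.7% with FGF and 85.0 to 89.2% with the combination.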

Other observations

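The genes of iron handling, and the comparison of taurine synthesis across groups, were chosen after their values were seen, and no test of an explanation was run on them. Hamp, the gene of the iron hormone hepcidin, had 25.6 ± 10.3 FPKM in Null and 8.15 ± 10.1 in GSK livers (SD, n = 5 each; log2 difference -2.54, limma adjusted p = 0.368), in the group whose erythroid genes were higher as a list. Between GSK and combination livers Hamp rose by 3.36 (adjusted p = 0.00691) and the globin gene Hbb-bs fell by 1.81 on the log2 scale (adjusted p = 0.00555). Hamp ran from 0 to 19.9 FPKM in the GSK libraries, and its call was lost in a fit of the compared groups alone. With the diet Hamp had 64.6 FPKM in Chow and 25.6 in Null livers (log2 difference -1.24, adjusted p = 0.166), while the related gene Hamp2 rose by 2.86 (adjusted p = 0.0145), the iron exporter gene Slc40a1 by 1.21 (adjusted p = 2.85e-05), and the ferritin genes Fth1 by 0.71 (adjusted p = 0.00436) and Ftl1 by 1.01 (adjusted p = 0.000801). In the combination against Null Slc40a1 fell by 0.60 (adjusted p = 0.0305) and Fth1 by 0.86 (adjusted p = 0.00277).

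Csad, which makes the taurine used to conjugate bile acids, had 131 FPKM in Chow, 80.0 in Null, 139 in GSK, 33.1 in FGF and 11.1 in combination livers. Against Null it fell by 1.47 on the log2 scale with FGF (limma adjusted p = 0.0397; no gene was called there without Null replicate 4, FGF replicate 2 or FGF replicate 3, a count of 0 each) and by 2.82 with the combination (adjusted p = 2.83e-05).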
